A study of Macaca mulatta with 64 samples.

How the data were processed

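The series measured polyadenylated RNA of the rhesus macaque brain by directional RNA sequencing. The 64 libraries cover 8 regions at 4 ages (1, 4, 10 and 20 years) in 2 sexes, with 1 library for each region, age and sex. Per the labels' protocols the tissue came from 16 animals, 4 per age and 2 per age and sex. Whether the RNA of both animals was pooled in a library is not given in the sources used here. The 8 combinations of age and sex are called animal sets and served as the replicates. The p-values of the age and sex fits therefore measure the spread between 8 animal sets, not between 16 single animals. Those of region contrasts and of slope differences between regions measure what is left once the animal set is taken out. That spread is pooled over all regions in the fit.

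The values used were RPKM (reads scaled to the length of the transcript and the total of the library), deposited by the authors as a single table of 26654 genes by 64 libraries. Per the submitters' processing notes the tools were TopHat2, Cufflinks 2.2 and edgeR, with no role stated for any of them. The genome build, the annotation and the counting of reads per gene are not given in the sources used here. Each gene carried an identifier, and 20219 also carried a symbol. Of the 6435 genes without a symbol, 1480 passed the filter. Some symbols had been turned into calendar dates, as spreadsheets do, and were not repaired. The table did not mark coding and long noncoding genes, and none of 18 long noncoding RNAs looked up by name was matched, so long noncoding RNAs were not analysed here as a class. Columns of per-sample values not used numbered 0.

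Read counts were not used here, so the depth of each library is unknown. Total RPKM per library ran from 322364 to 567934. The size of 1 read could be traced in part. Values of 640 copies of the U6 small nuclear RNA lay on whole multiples of a step, within 0.006 RPKM and below 1.5 RPKM, for 50.6% to 70.6% of values in libraries of 5 regions, with steps of 0.079 to 0.185 RPKM. In the libraries of the other 3 regions 22.7% to 41.9% did so, too few to read a step from them. Values of 0 were handled as listings of 0, since genes used by nearly every cell were among them.

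Tests were run in R 4.3.3 with limma 3.58.1 (linear models with empirical Bayes moderation and an intensity trend) and data.table (version 1.17.8), on log2(RPKM + 1). Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. The pseudocount of 1 makes fold changes of low genes smaller than they are. Genes were kept when they reached at least 1 RPKM in at least 8 libraries, which left 14414. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, at a threshold of 0.05. A region call also required a difference of at least 1 on the log2 scale. The planned region contrasts used all 64 libraries with the animal set as a fixed block. The age trend was the slope of log2 level per doubling of age over 8 values per gene, the mean over the 8 regions of each animal set, with sex as a covariate. The sex difference came from the same fit. Age within a region was fitted to its 8 libraries alone. Differences of age slopes or of sex effects between regions were tested within animal sets on all 64 libraries. These tests, the filter, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

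The pairing of libraries by animal set was checked from deviations from the region means. Libraries of 1 animal set from different regions had a mean correlation of 0.33, with 209 of 224 pairs above 0.1. Libraries of different sets had a mean of -0.046, which follows from centring on the region means once libraries of a set correlate. The best match of 62 of 64 libraries in another region was a library of the own set. Age and sex, which a set shares by definition, were left in these values. With a slope on log2 age and sex taken out, the mean correlation within a set was 0.22 to 0.34. The labels do not say that libraries of a set share animals, and the block had been fixed in the design. No 2 libraries held identical values, and the highest correlation between libraries of a region was 0.994.

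The cerebellar, occipital and temporal libraries stood apart from the other 40 libraries in how low and high genes were filled. Region contrasts within each of these sets of libraries were therefore added after the data were seen, and so was the contrast of the dentate gyrus slope with the other 7. The contrasts within a set were fitted to its libraries alone, with the filter of at least 1 RPKM in at least 8 libraries applied to them, which left 14083 genes in the first set and 12039 in the second. In the fits within a region, genes with 1 constant value stayed in, as the design had it. The fits without them were run later, and both sets of counts were seen.

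The 31 gene lists tested hold markers of brain cell types, regional transcription factors, synaptic and other functional groups, and X genes known to escape inactivation. Each was tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, all in limma, adjusted over the lists of a contrast. A list of blood genes had 1 member kept and a list of Y chromosome genes 2, and neither was tested. Counts of members are given over all genes and adjusted over the list alone. GAD1 appears in the table as GAD67 and PPP1R17 as C7ORF16.

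Named genes were kept genes with a symbol carried by 1 identifier and at least 5 RPKM in the higher group. For the cerebellar contrast the rule took the 10 highest and 10 lowest differences among called genes with the same direction in all 8 animal sets. It took 8 and 8 for the hippocampal, dentate and occipital contrasts and 3 and 3 for the other neocortical ones. For age it took the 12 highest and 12 lowest slopes among called genes whose 20-year value lay on the same side of the 1-year value in both sexes, and for sex 10 and 10. Where under 5 genes were called in a direction, the 5 smallest p-values are named as not called, and for interactions the 5 smallest p-values. The added contrasts used the numbers of their planned counterparts, and the cerebellar and dentate slopes took 8 and 8 besides. Members of the lists are named in addition. Some genes that the rule or a list would name are not reported here. Levels are means of RPKM over the 8 animal sets with their SD, and differences of log2 level are given with their SE.

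Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 RPKM, median-ratio scaling, quantile normalization, robust variance moderation, no block, age per year or as levels, other groups of regions, and each animal set left out in turn, for slopes of list means too. On simulated data with 200 of 14414 genes changed, the age trend test recovered 86.5% of slopes of 0.2 and 98.5% of slopes of 0.5. The sex test recovered 69.5% of differences of 0.5 and 98.5% of differences of 1.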

Results

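RNA from 8 regions of the rhesus macaque brain was sequenced at 1, 4, 10 and 20 years of age in both sexes, to follow expression across space, age and sex. The regions were the cerebellar cortex, the occipital (primary visual), temporal, prefrontal, posterior cingulate and parietal cortex, and 2 parts of the hippocampal formation, CA1 and the dentate gyrus. Each region gave 8 libraries, 1 for each of the 8 animal sets defined by age and sex. The number of reads per library is unknown here, and total RPKM per library lay between 322364 and 567934. The 10 mitochondrially encoded genes took 6.31% to 18.5% of it and the 100 highest genes 35.1% to 67.3%.

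The libraries fell into 2 sets that followed region and not age or sex. All 24 libraries of the cerebellar, occipital and temporal cortex (the first set) had 13234 to 13480 genes at 1 RPKM or more, and the 40 libraries of the other regions (the second set) had 10645 to 11521. The median over all genes was 0.95 to 1.07 RPKM in the first set and 0.32 to 0.45 in the second. Genes used by nearly every cell were listed at 0 in all 40 libraries of the second set. Among these was CFL1, which encodes the actin-severing protein cofilin and had a mean of 372 RPKM in the first set. Others were RPS27, a ribosomal protein (172 RPKM), and SERINC1, a membrane protein (194 RPKM). In all, 262 genes of at least 10 RPKM in the first set were listed at 0 throughout the second. By contrast 84.9% of the 1561 genes at 1 to 2 RPKM in the first set were above 0 in all 40 libraries. The temporal cortex correlated better with the cerebellar cortex (mean Spearman rho across genes 0.826) than with the parietal cortex (0.804) in 8 of 8 animal sets. These correlations are across genes, which are not independent replicates. Contrasts between regions of different sets therefore hold this difference as well as that between the tissues. Contrasts within a set come first in what follows, with the planned contrasts beside them. Age and sex were balanced over both sets.

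**Figure D1:**
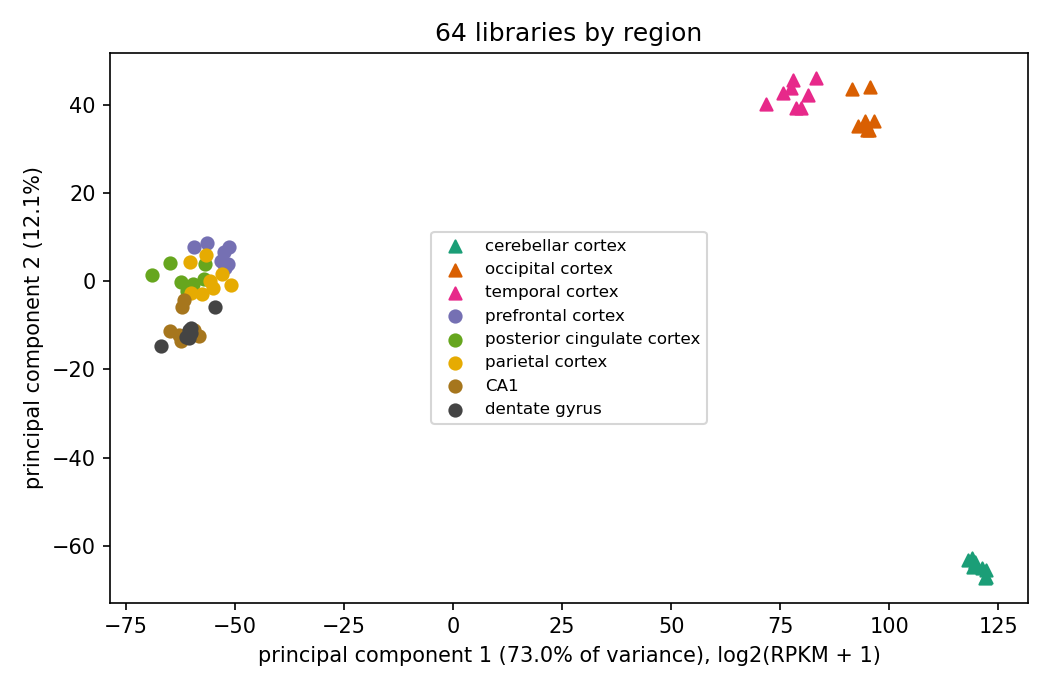
Each point is 1 of 64 libraries on the first and second principal components of log2(RPKM + 1), which held 73.0% and 12.1% of the variance; triangles are the first set (cerebellar, occipital and temporal cortex) and circles the second. On the first component the first set lay between 71.8 and 122 and the second between -68.9 and -51.0.

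The cerebellar cortex was compared with the forebrain to describe the genes that set it apart. Against the occipital and temporal cortex of the same set, genes of cerebellar granule neurons were highest. CBLN3 and CBLN1, secreted synapse organizers of granule cells, stood at 187 ± 19.8 and 382 ± 73.8 RPKM in the cerebellar cortex against 0.271 ± 0.123 and 2.2 ± 0.814 (SD, n = 8 animal sets). GABRA6, the granule cell GABA-A receptor subunit, reached 127 ± 13.9 RPKM against 0.031 ± 0.013, a log2 difference of 6.95 ± 0.05 (SE, limma adjusted p = 1.6e-26). PCP2, a Purkinje cell protein, reached 143 ± 28.4 RPKM. DOK7, CNPY1, the glutamate receptor GRM4, the midbrain-hindbrain factor EN2, ZIC4 and CDR1 completed the 10 highest, with log2 differences of 5.41 to 6.58. Lowest was NRGN, the calmodulin-binding protein neurogranin of forebrain neurons, with 0.93 ± 0.36 against 1448 ± 293 RPKM, a log2 difference of -9.54 ± 0.08 (adjusted p = 8.8e-26). DDN, RGS4, KIAA0748, the neuropeptides SST and CCK, CHGA, NGEF, the kinase CAMK2A and FXYD7 followed with log2 differences of -6.83 to -5.28, and CAMK2A stood at 4.95 ± 1.02 against 309.6 ± 26.7 RPKM.

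All 10 measured members of the list for cerebellar granule neurons were higher in the cerebellar cortex, among them ZIC1 (log2 difference 5.38), BARHL1 (4.35) and PAX6 (2.63), and the list stood above other genes (camera adjusted p = 7.6e-07, and adjusted p = 0.039 with an estimated correlation). Of 7 hindbrain and cerebellar transcription factors 6 were higher, including LHX1 (4.05) and LHX5 (1.55), while IRX2 (0.40) did not pass (list adjusted p = 0.00083, and adjusted p = 0.044 with an estimated correlation). Of 8 forebrain transcription factors 7 were lower, such as EMX1 (-3.90), LHX2 (-4.12) and EMX2 (-2.46), and NEUROD2 was higher (1.64 ± 0.07), with an adjusted p of 5.1e-05 for the list and adjusted p = 0.022 with an estimated correlation. Of 10 excitatory neuron genes 8 were lower, including TBR1 (-3.38), RORB (-3.89) and CUX2 (-2.67), while the glutamate transporters SLC17A7 (-0.30) and SLC17A6 (-0.86) stayed under the size of 1 (adjusted p = 7.6e-07, and adjusted p = 0.0060 with an estimated correlation). Among 11 inhibitory neuron genes 6 were lower, such as NPY (-4.89), VIP (-2.95) and LHX6 (-2.61), and the calcium-binding PVALB (2.54 ± 0.15) and CALB2 (2.05 ± 0.20) were higher (adjusted p = 0.00068, and adjusted p = 0.016 with an estimated correlation). Of 8 Purkinje cell genes 5 were higher, among them SLC1A6 (2.79), CA8 (2.76) and CALB1 (2.35), with an adjusted p of 0.0025 and adjusted p = 0.086 with an estimated correlation. The counts adjusted over the list alone were equal to these. Microglial genes (1 of 7 lower, median -0.69) and genes of endothelium and pericytes (1 of 10 lower, median -0.40) were also lower as lists, with adjusted p of 0.0060 and 0.0048, and their adjusted p = 0.16 and 0.15 with an estimated correlation. Median-ratio scaling and quantile normalization turned the median of none of these lists.

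In this contrast limma called 2375 of 14083 genes, 1272 higher and 1103 lower, and 2367 of the calls had the same direction in all 8 animal sets, which are the sets the calls were made on. Among genes with a mean of at least 5 RPKM 1578 were called, and 2467 in the planned contrast below. With median-ratio scaling, which moved the median difference of all genes from 0.15 to 0.00, the split was 979 higher and 1313 lower. The planned contrast with all 7 forebrain regions called 4656 of 14414 genes, 4055 higher and 601 lower, of which 541 were listed at 0 in the second set. The same genes led it (NRGN -9.18, GABRA6 6.96, CBLN3 7.14), joined by RBPMS at 1044 against 364 RPKM. The split of the planned contrast was 2357 and 1198 with median-ratio scaling and 1880 and 1588 with quantile normalization, which moved the median difference from 0.50 to 0.04 and -0.14.

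The primary visual cortex was compared with the temporal cortex, the other neocortical area of the first set. PVALB, the calcium-binding protein of fast-spiking interneurons, stood at 124 ± 23.5 RPKM in the occipital and 21.4 ± 8.64 in the temporal cortex (log2 difference 2.57 ± 0.18, limma adjusted p = 9.5e-10). HPSE2, a heparanase relative, stood at 29.4 ± 6.78 against 1.51 ± 0.61 RPKM (3.61 ± 0.10). OSTN, TMEM215, LTB, FSTL1 and KCNH8 were also higher, by 2.19 to 2.48. NECAB2 (5.09 ± 1.88 against 70.2 ± 16.2 RPKM) and the retinol carrier RBP4 (8.06 ± 4.84 against 84.9 ± 15.96) were lower. CRYM, a thyroid hormone binding protein (12.8 ± 4.204 against 82.7 ± 13.7), and the neuropeptide gene CARTPT (1.22 ± 0.93 against 14.1 ± 8.80) were lower. So were RASAL1, PNMA5 and ELMSAN1, with log2 differences of -2.70 to -2.55.

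Among 13 oligodendrocyte and myelin genes 7 were higher in the occipital cortex, including MBP (log2 difference 1.48 ± 0.22), the myelin basic protein, MOG (1.22) and MAG (1.23), with a camera adjusted p of 0.0010 and adjusted p = 0.52 with an estimated correlation. Among 11 inhibitory neuron genes SST (-1.53), LAMP5 (-1.43), NPY (-1.06) and CALB2 (-1.96) were lower while PVALB was higher (adjusted p = 0.0048, and adjusted p = 0.091 with an estimated correlation). Microglial genes had a median of -0.45 with 0 of 7 members called (adjusted p = 0.00028, and adjusted p = 0.12 with an estimated correlation). Of 9 mitochondrially encoded genes 1 was lower (adjusted p = 0.00028, and adjusted p = 0.36 with an estimated correlation). Counts adjusted over the list alone were the same. In all, limma called 400 of 14083 genes, 209 higher and 191 lower, 391 of them the same way in all 8 sets, and 694 with a pseudocount of 0.1. The split was 156 and 230 with median-ratio scaling and 165 and 228 with quantile normalization.

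CA1 and the dentate gyrus together were compared with the prefrontal, posterior cingulate and parietal cortex of the same set. TTR, the thyroxine carrier that the choroid plexus secretes, stood at 379 ± 225 RPKM in the hippocampal regions and 3.87 ± 1.99 in the neocortex (log2 difference 5.99 ± 0.26, limma adjusted p = 2.3e-19). The neurotrophin gene NTF3 stood at 7.06 ± 1.99 against 0.249 ± 0.066 RPKM (2.48 ± 0.07), and MOBP, a myelin protein, at 93.2 ± 26.8 against 20.0 ± 5.84 (1.92 ± 0.12), of which MOBP was called in CA1 alone (2.99) and not in the dentate gyrus alone (0.86). CABP7, ZCCHC12, BHLHE22, GPD1 and ERMN were higher by 1.91 to 2.83. Lower were KIAA0748 (6.86 ± 6.08 against 95.3 ± 9.95 RPKM, -4.59 ± 0.26), MEPE (-3.54), the G protein regulator RGS4 (-3.14), MYOC (-2.65), CRABP2 (-2.49), RIMS3 (-2.44), the secreted WNT inhibitor SFRP2 (-2.33) and the potassium channel gene KCNS1 (-2.30).

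All 12 measured oligodendrocyte and myelin genes were higher in the 2 hippocampal regions together, among them MOG (log2 difference 1.64), OPALIN (1.68) and MBP (1.62), with a camera adjusted p of 1.0e-09 and adjusted p = 0.23 with an estimated correlation. With each region set alone against the same neocortex, 12 of 12 were higher in CA1 (median 2.12) and 1 of 12, ERMN, in the dentate gyrus (median 0.53). MBP stood at 3489 RPKM in CA1, 772 in the dentate gyrus, 781 in the posterior cingulate, 766 in the parietal and 320.4 in the prefrontal cortex. Of 6 choroid plexus and ependyma genes TTR, AQP1 (1.33) and FOLR1 (1.17) were higher (adjusted p = 0.00073, and adjusted p = 0.23 with an estimated correlation). Lower were 4 of 9 immediate early genes, which neurons switch on with activity, EGR1 (-1.31), NR4A1 (-1.23), DUSP1 (-1.11) and EGR2 (-1.05), with adjusted p = 0.00020 and adjusted p = 0.23 with an estimated correlation. These 4 were called in the dentate gyrus alone, and in CA1 alone they stood at -0.92 to -0.79, under the size of 1. Of 11 inhibitory neuron genes PVALB (-1.99), VIP (-1.35), DLX1 (-1.16) and SLC32A1 (-1.09) were lower (adjusted p = 0.00050, and adjusted p = 0.23 with an estimated correlation). The 3 measured genes of the list for CA1 pyramidal neurons, WFS1 (-1.03), MPPED1 (-1.24) and NOV (-1.01), were lower in the 2 regions together (adjusted p = 0.021, and adjusted p = 0.23 with an estimated correlation), and all 3 were called in the dentate gyrus alone, while in CA1 alone they stood at -0.78 to -0.51, under the size of 1. Of the meninges list COL1A1 (-1.04) and DCN (-1.24) were lower (2 of 3, adjusted p = 0.011, and adjusted p = 0.23 with an estimated correlation). Counts adjusted over the list alone were the same. In all, 352 of 12039 genes were called by limma, 140 higher and 212 lower, 346 of them the same way in all 8 sets. The count was 748 with a pseudocount of 0.1 and 206 among genes with a mean of at least 5 RPKM, and CA1 alone had 366 and the dentate gyrus alone 510. The planned contrast with all 5 neocortical areas called 1334 genes, 100 higher and 1234 lower, of which 352 were listed at 0 in the second set, and 2537 with a pseudocount of 0.1. Its split was 213 and 869 with median-ratio scaling and 253 and 715 with quantile normalization, which moved the median difference from -0.24 to -0.02 and 0.08.

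The dentate gyrus was compared with CA1, the only planned region contrast within a set. NPY1R, a neuropeptide Y receptor, was higher in the dentate gyrus (24.3 ± 7.63 against 4.67 ± 2.00 RPKM, log2 difference 2.16 ± 0.15, limma adjusted p = 6.7e-17). So were C1QL3, a secreted C1q relative at synapses (21.9 ± 7.47 against 5.50 ± 2.94, 1.86 ± 0.16), and the peptide gene GRP (21.2 ± 6.47 against 5.56 ± 2.91, 1.83 ± 0.22). SLN, VWA5A, ZCCHC12, TSPAN18 and TANC1 were higher by 1.44 to 1.69. Lower were the myelin genes MOBP (34.9 ± 14.2 against 152 ± 45.0 RPKM, -2.13 ± 0.20) and MOG (19.9 ± 7.87 against 77.0 ± 25.4, -1.93), the oligodendrocyte genes NKX6-2 (-1.97) and GJB1 (-1.93), and STARD13 (-1.88). IRX2 (4.98 ± 1.56 against 60.2 ± 61.1 RPKM), KLHL34 and SPNS1 were lower by log2 differences of -2.73, -2.71 and -2.48, with CA1 levels that spread widely between animal sets.

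Of 13 oligodendrocyte and myelin genes 12 were lower in the dentate gyrus than in CA1, including MBP (log2 difference -2.21) and CNP (-1.75), with a camera adjusted p of 2.2e-12 and adjusted p = 0.15 with an estimated correlation. MBP stood at 3489 ± 931 RPKM in CA1 and 772 ± 282 in the dentate gyrus. Of 7 oligodendrocyte precursor genes SOX10 (-1.34) and OLIG1 (-1.29) were lower (adjusted p = 0.0013, and adjusted p = 0.11 with an estimated correlation). The 5 measured genes of dentate granule neurons had a median of 0.95 and 0 calls, because PROX1, the granule cell transcription factor (0.95 ± 0.08, adjusted p = 5.2e-14), C1QL2 (0.95 ± 0.15) and TRPC6 (0.95 ± 0.07) lay just under the size of 1 (list adjusted p = 0.0039, and adjusted p = 0.11 with an estimated correlation). Microglial genes had a median of -0.51 and 0 calls (adjusted p = 0.0062, and adjusted p = 0.45 with an estimated correlation). Counts adjusted over the list alone were the same. In all, 249 genes were called by limma, 74 higher and 175 lower, 223 of them the same way in all 8 sets, and 599 with a pseudocount of 0.1.

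The prefrontal, posterior cingulate and parietal cortex were each compared with the mean of the other 2, and few genes were called. In the prefrontal cortex MOBP stood at 9.60 ± 3.53 against 25.3 ± 7.59 RPKM (log2 difference -1.31 ± 0.16, limma adjusted p = 7.7e-07), ERMN at 9.58 ± 4.69 against 23.9 ± 11.5 (-1.19) and GJB1 at 2.87 ± 1.67 against 7.94 ± 4.51 (-1.14). CRYM was higher there, 79.6 ± 10.2 against 37.1 ± 8.15 RPKM (1.12 ± 0.13). Of 12 oligodendrocyte and myelin genes 5 were lower in the prefrontal cortex, with a median of -0.85 (camera adjusted p = 1.7e-22, and adjusted p = 0.056 with an estimated correlation). The same list had medians of 0.35 in the posterior cingulate and 0.45 in the parietal cortex with 0 members called (adjusted p = 1.4e-08 and 7.8e-09, and adjusted p = 0.47 and 0.76 with an estimated correlation). Mitochondrially encoded genes had a median of -0.28 in the prefrontal cortex (adjusted p = 1.4e-09, and adjusted p = 0.18 with an estimated correlation) and 0.31 in the posterior cingulate cortex, the latter -0.01 under quantile normalization (adjusted p = 8.9e-12, and adjusted p = 0.16 with an estimated correlation). HOXA10, SPNS1 and ELMSAN1 were lower in the posterior cingulate cortex (23.4 ± 9.87 against 84.7 ± 41.5 RPKM for SPNS1, -1.71 ± 0.32) and higher in the parietal cortex (99.5 ± 39.2 against 46.7 ± 26.6 for SPNS1, 1.33 ± 0.32, adjusted p = 0.0105). In the parietal cortex CBLN2 (12.8 against 22.7 RPKM, -0.79 ± 0.12), RBP4 (-0.70), PLCH2, PCDH17 and CRIP2 had the smallest p among lower genes and did not reach the size of 1.

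In limma these contrasts gave 23 calls for the prefrontal (8 higher, 15 lower), 19 for the posterior cingulate (8 higher, 11 lower) and 5 for the parietal cortex, SPNS1, ELMSAN1, HOXA10, KLHL34 and IRX2, all higher and the last 2 named after their values were seen. Of them 16, 16 and 5 had the same direction in all 8 sets. The prefrontal split was 5 and 22 with median-ratio scaling and 5 and 21 with quantile normalization, and median-ratio scaling moved the median difference from 0.11 to 0.00 there and from -0.11 to 0.00 in the posterior cingulate cortex. With a pseudocount of 0.1 the counts were 61, 54 and 22. The parietal count was 3 with no filter, 1 without the 4-year males, 2 without the 10-year or the 20-year males, 3 without the 20-year females and 2 with no block. The planned contrasts of single areas with the other neocortex followed the 2 sets. Of the calls, 2718 of 2790 calls in the occipital and 1826 of 1840 in the temporal cortex were higher. Conversely 1072 of 1083 in the prefrontal, 1399 of 1412 in the posterior cingulate and 1152 of 1164 in the parietal cortex were lower. RBPMS, BEX4 and PLEKHA8 led each of these except in the parietal cortex, where BEX2 stood in the place of PLEKHA8, and BEX4 and BEX2 were listed at 0 throughout the second set. Calls listed at 0 in the second set numbered 501 in the occipital, 479 in the temporal and 409 in each of the other 3 contrasts. With quantile normalization the counts were 1603 in the occipital (1271 and 332), 1081 in the temporal, 713 in the prefrontal, 768 in the posterior cingulate and 711 in the parietal cortex. With a pseudocount of 0.1 they were 2921 in the temporal, 1928 in the prefrontal, 2628 in the posterior cingulate and 2030 in the parietal cortex. Among genes with a mean of at least 5 RPKM they were 1485 in the occipital, 663 in the prefrontal, 892 in the posterior cingulate and 732 in the parietal cortex. The median differences moved from 0.38 to -0.21 (occipital), 0.29 to -0.20 (temporal), and -0.14, -0.31 and -0.23 to 0.13 in each of the prefrontal, posterior cingulate and parietal contrasts with quantile normalization. The mitochondrially encoded ATP8 also followed the 2 sets, lower in the occipital (149 against 1563 RPKM) and temporal cortex and higher in the other 3 areas. MYOC was higher in the prefrontal cortex (23.0 against 8.81 RPKM).

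Expression was then followed from 1 to 20 years of age. Over the mean of the 8 regions ERMN, a myelin cytoskeleton protein, stood at 17.2 RPKM at 1 year and 41.1 at 20 years, a slope of 0.33 ± 0.06 log2 units per doubling of age (SE, n = 8 animal sets, limma adjusted p = 0.011). QDPR, an enzyme of tetrahydrobiopterin recycling, stood at 43.4 RPKM at 1 year and 89.3, 105 and 120 at 4, 10 and 20 years (0.34 ± 0.04, adjusted p = 0.0016). VAMP1, a vesicle fusion protein, went from 4.21 to 15.1 RPKM (0.35 ± 0.02, adjusted p = 0.00037) and NEFH, the heavy neurofilament of axons, from 33.4 to 99.9 (0.32). CNDP1, NKX6-2, GJB1, KLK6, HAPLN2, MYOC, HSPB8 and LTB also rose, by 0.29 to 0.42. Among falling genes IGFBP3, an insulin-like growth factor binding protein, went from 13.3 RPKM at 1 year to 3.28 at 20 years (-0.39 ± 0.08). ARC, an activity-induced synaptic gene, went from 20.1 to 5.61 (-0.30 ± 0.03), EGR1 from 31.9 to 12.9 (-0.25 ± 0.03), MEIS3 from 48.3 to 17.7 (-0.37) and FAM19A1 from 174 to 51.5 (-0.27 ± 0.02). C5ORF13, SLC16A1, ARHGAP10, MMD, KCNG1, PVRL3 and B4GALT2 fell by 0.24 to 0.29.

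Of 13 oligodendrocyte and myelin genes 10 rose with age (11 adjusted over the list alone), among them MBP (0.27 ± 0.06), MAG (0.26 ± 0.04) and MYRF, the transcription factor of myelination (0.24 ± 0.03), while MOBP (0.08) and CLDN11 (0.05) were among those that did not pass over all genes. The list had a median slope of 0.19, with a camera adjusted p of 7.7e-06 and adjusted p = 0.40 with an estimated correlation. Of 13 glutamate receptor and postsynaptic density genes 5 fell (6 adjusted over the list alone), HOMER1 (-0.18 ± 0.03), GRIN2A (-0.11), GRIN2B (-0.10), SHANK2 (-0.10) and GRIA4 (-0.08), with adjusted p = 1.2e-05 and adjusted p = 0.28 with an estimated correlation. Of 13 GABA-A receptor subunits 4 fell (5 adjusted over the list alone), including GABRA2 (-0.13) and GABRA5 (-0.11), with adjusted p = 0.0026 and adjusted p = 0.28 with an estimated correlation. Of 11 immediate early genes 5 fell, ARC, EGR1, NR4A1 (-0.21), EGR2 (-0.17) and NPAS4 (-0.08), and adjusted over the list alone 5 fell and 1 rose (adjusted p = 1.8e-05, and adjusted p = 0.28 with an estimated correlation). Of 11 genes of immature neurons 5 fell in both counts, over all genes and adjusted over the list alone, led by SOX11 (-0.27 ± 0.03) and DPYSL3 (-0.17), with adjusted p = 0.0026 and adjusted p = 0.28 with an estimated correlation. Of 8 Purkinje cell genes 2 fell, CALB1 (-0.21) among them (adjusted p = 0.028, and adjusted p = 0.37 with an estimated correlation). Of 5 perineuronal net genes HAPLN1 (-0.09), BCAN (-0.10) and NCAN (-0.10) fell and HAPLN4 rose (0.18), with adjusted p = 0.047 and adjusted p = 0.28 with an estimated correlation. For the last 2 lists the counts adjusted over the list alone were the same.

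**Figure D2:**
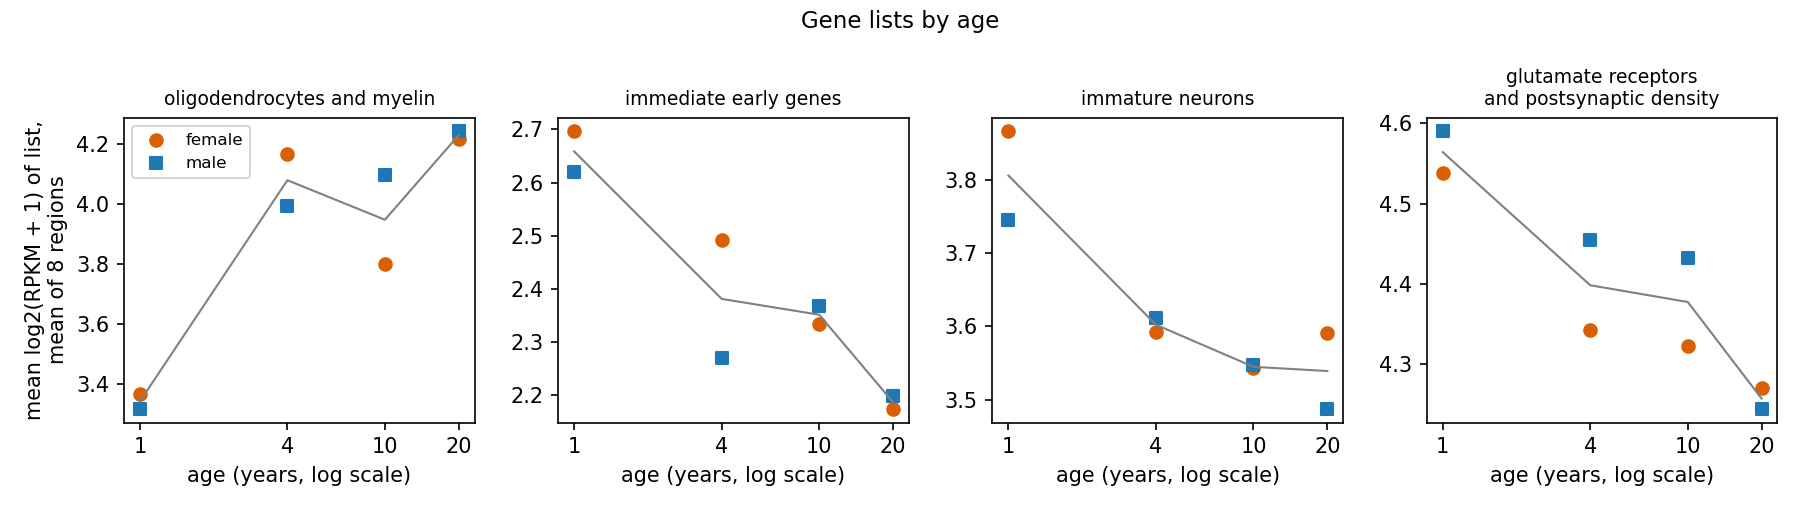
Mean log2(RPKM + 1) over 8 regions for 4 gene lists at 1, 4, 10 and 20 years; each point is an animal set (circles female, squares male) and the line is the mean of both sexes. The oligodendrocyte and myelin list had a median slope of 0.19 per doubling of age, and the other 3 lists (immediate early genes, immature neurons, glutamate receptors and postsynaptic density) had negative slopes.

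Other lists did not pass camera for age. Among 11 astrocyte genes GFAP (0.24 ± 0.04) and FGFR3 (0.08) rose and SLC1A3 fell (-0.07), and adjusted over the list alone 4 rose and 1 fell (adjusted p = 0.50). Of 7 complement genes C1S (0.13), SERPING1 (0.12) and C2 (0.09) rose (adjusted p = 0.15), of 3 proliferation genes TYMS (0.22) and MCM2 (0.08) rose (0.084), and of 6 choroid plexus genes CLIC6 (-0.22) and FOLR1 (-0.06) fell (0.051). Of 10 excitatory neuron genes 3 fell (median 0.00, mean -0.02, adjusted p = 0.15), among 11 inhibitory neuron genes 2 rose and 1 fell (0.084), and 1 of 8 microglial genes fell (0.35). No member of the lists for endothelium, meninges, hindbrain transcription factors, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins and cell cycle arrest was called by limma, and their camera adjusted p lay between 0.35 and 0.97.

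In all, limma called 2242 of 14414 slopes per doubling of age, 1446 up and 796 down. Per year of age 15 were called (11 up, 4 down, 3036 at an unadjusted p under 0.05). The count was 1414 with no filter, 3823 with the animal set as a random effect over 64 libraries, and 6888 with these libraries as independent, which counts animals more than once. The split was 897 up and 1309 down with median-ratio scaling and 994 and 1215 with quantile normalization. The calls did not hold without the youngest animals, whose loss also leaves fewer values and a shorter range of ages. Without the 1-year sets 1 gene was called (1241 at an unadjusted p under 0.05) and none of the 24 named genes kept its call. The count was 539 without the 1-year females, 584 without the 1-year males, 1167 without the 20-year females and 552 without both 20-year sets. With age as 4 levels, 16 genes differed between 4 and 1 years, and in limma 0 did between 10 and 4 years (1542 at an unadjusted p under 0.05) and 0 between 20 and 10 years (726). In the list tests without the 1-year sets 12 of 30 lists passed camera with 0 members called by limma, among them oligodendrocytes and myelin (median 0.07, adjusted p = 0.038), glutamate receptors (-0.05, 0.0041), immediate early genes (-0.06, 0.0066) and astrocytes (0.06, 0.0041). None passed with an estimated correlation (adjusted p = 0.35 with an estimated correlation for the lowest).

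The trend was then fitted in each region alone. Of 13 oligodendrocyte and myelin genes 8 rose in the occipital, 9 in the posterior cingulate, 7 in the parietal, 4 in the cerebellar, 2 in the prefrontal, 1 in the temporal cortex and 0 in CA1 and the dentate gyrus in limma (11, 10, 11, 6, 9, 12, 0 and 0 adjusted over the list alone). The camera adjusted p of the list lay between 3.3e-07 and 0.0061 in the first 6 of these regions, with adjusted p = 0.47, 0.55, 0.37, 0.61, 0.78 and 0.35 with an estimated correlation. The mean slope of the list was 0.25 in the occipital, 0.28 in the temporal and 0.29 in the parietal cortex, 0.066 ± 0.072 in CA1 and 0.026 ± 0.10 in the dentate gyrus. Without the 1-year male library it was 0.17 ± 0.14 in the temporal cortex and 0.0014 ± 0.086 in CA1, which had 0.11 without the 20-year female library, and without single libraries it lay between -0.021 and 0.071 in the dentate gyrus. Of 13 glutamate receptor and postsynaptic density genes 7 fell in the occipital, 3 in the temporal, 4 in the prefrontal, 2 in the posterior cingulate and 1 in the parietal cortex (12, 9, 5, 3 and 5 adjusted over the list alone). The camera adjusted p of the list lay between 8.4e-10 and 0.0027 in these 5 areas, with adjusted p = 0.27, 0.20, 0.098, 0.55 and 0.32 with an estimated correlation. Of 11 immediate early genes 5 fell in the occipital, 5 in the temporal and 3 in the prefrontal cortex (8, 7 and 4 adjusted over the list alone), with adjusted p = 5.9e-07, 3.7e-05 and 0.0040 and adjusted p = 0.34, 0.17 and 0.68 with an estimated correlation. From 1 to 20 years the list mean also went from 2.94 to 2.21 in females and 2.94 to 2.13 in males in the parietal cortex. It went from 2.38 to 1.68 and 2.27 to 1.59 in CA1, but from 1.90 to 2.03 and 2.00 to 1.96 in the cerebellar cortex. Of 8 Purkinje cell genes 3 fell in the cerebellar cortex (6 adjusted over the list alone, adjusted p = 0.0035, and adjusted p = 0.61 with an estimated correlation). The fall was not particular to the cerebellar cortex: the mean slope of this list was -0.094 ± 0.032 there and -0.107 ± 0.019 in the occipital cortex. It was -0.064 to -0.037 in the other neocortical areas, 0.033 in CA1 and 0.0013 in the dentate gyrus.

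**Figure D3:**
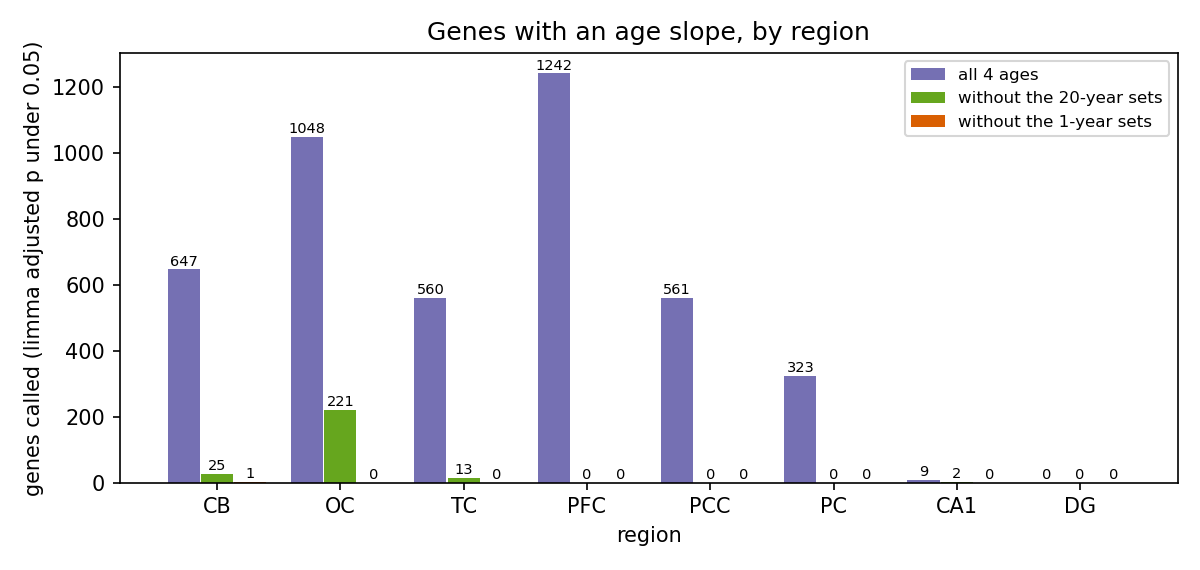
Number of genes with a called age slope in each region, fitted to its 8 libraries (all 4 ages), to 6 libraries without the 20-year sets, and to 6 libraries without the 1-year sets. With all ages the counts ran from 0 in the dentate gyrus to 1242 in the prefrontal cortex, and without the 1-year sets from 0 to 1.

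Called slopes numbered 1242 in the prefrontal (903 up, 339 down), 1048 in the occipital (525 and 523), 647 in the cerebellar (361 and 286), 561 in the posterior cingulate (452 and 109), 560 in the temporal (329 and 231) and 323 in the parietal cortex (232 and 91). CA1 had 9 (4 and 5, with 2904 at an unadjusted p under 0.05) and the dentate gyrus 0 in limma (3483 at an unadjusted p under 0.05). The dentate count was 43 with median-ratio scaling (15 up, 28 down), 69 with quantile normalization (26 and 43), 11 among genes with a mean of at least 5 RPKM (2 and 9) and 10 with robust variances (0 and 10). The CA1 count was 15 among genes with a mean of at least 5 RPKM, 25 with robust variances and 2 with no filter. With genes of 1 constant value in the region left out, the counts were 49 in the dentate gyrus (6 and 43), 225 in CA1 (133 and 92), 2043 in the prefrontal, 1039 in the posterior cingulate and 896 in the parietal cortex. With median-ratio scaling the splits were 554 and 785 in the prefrontal, 395 and 747 in the occipital, 262 and 399 in the cerebellar, 198 and 234 in the posterior cingulate and 268 and 422 in the parietal cortex, with 3 and 6 in CA1. With quantile normalization they were 728 and 792 in the prefrontal, 310 and 308 in the posterior cingulate and 320 and 440 in the parietal cortex, with 2 and 4 in CA1. With no filter on low genes the occipital count was 0 (4204 at an unadjusted p under 0.05) and the prefrontal 318, the posterior cingulate 111, the temporal 15, the parietal 6 and the cerebellar 2. Among genes with a mean of at least 5 RPKM the temporal count was 368. Without both 20-year libraries the counts were 25 in the cerebellar, 221 in the occipital and 13 in the temporal cortex, 2 in CA1, and by limma 0 in the prefrontal, posterior cingulate and parietal cortex (3551, 2201 and 2410 at an unadjusted p under 0.05). With robust variances the posterior cingulate count was 872 and the parietal 648. These counts changed when single libraries were left out, which also leaves fewer values for the fit. Without the 1-year female and the 1-year male library they were 50 and 97 in the cerebellar, 54 and 23 in the occipital, 66 and 138 in the temporal, 0 and 0 in the prefrontal, 1 and 1 in the posterior cingulate, and 0 and 0 in the parietal cortex, and 1 and 3 in CA1. Without the 20-year female library they were 202 in the cerebellar, 582 in the occipital, 249 in the temporal, 225 in the prefrontal, 2 in the posterior cingulate and 0 in the parietal cortex. Without the 20-year male library they were 626 in the occipital, 97 in the temporal, 199 in the prefrontal, 73 in the posterior cingulate and 2 in the parietal cortex and 1 in CA1. Without the 10-year female library they were 384 in the cerebellar, 368 in the prefrontal, 129 in the posterior cingulate and 23 in the parietal cortex and 2 in CA1. Without the 10-year male library they were 319 in the temporal, 739 in the prefrontal, 9 in the posterior cingulate and 0 in the parietal cortex and 4 in CA1. Without the 4-year female library they were 331 in the posterior cingulate and 573 in the parietal cortex and 2 in CA1, and without the 4-year male library 426 in the cerebellar and 672 in the prefrontal cortex and 4 in CA1.

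Age slopes differed between regions, and the dentate gyrus stood out. SAMD14, STAC2, EFHD2, HSPB8 and DOC2A had the smallest p of the age by region interaction (adjusted p = 1.5e-13 for SAMD14). DOC2A was listed at 0 throughout the second set, which set its slope to 0 in 5 regions before the test. SAMD14 went from 6.44 RPKM at 1 year to 21.5 at 20 years in the prefrontal cortex but from 11 to 6.85 in the dentate gyrus. GFAP, the intermediate filament of astrocytes, went from 172 to 647 RPKM in the prefrontal cortex and from 1164 to 710 in the dentate gyrus, whose slope differed from the mean of the other 7 regions by -0.49 ± 0.06 (limma adjusted p = 2.4e-07). TTR had a slope difference of -0.75 ± 0.14 and went from 513 to 76.7 RPKM in the dentate gyrus. SHD (-0.46), TMCC2 (-0.34), ARL9 (-0.35), LYPD1, SFRP2, RSPO3, LTB and RND2 were also lower in slope. Higher in slope were MEIS3 (0.47 ± 0.07), CALB1, the calcium-binding protein calbindin of granule cells (0.36 ± 0.06, adjusted p = 2.3e-05), SPON2, GSG1L, INHBA, KCTD8, NAALAD2 and NPTX2.

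In the dentate gyrus alone no gene was called by limma in the main setting, and 10 to 69 genes were in the 5 other settings given above, with 0 under a pseudocount of 0.1 or no filter. Of 11 astrocyte genes 9 fell adjusted over the list alone. GFAP stood at -0.19 ± 0.04 and AQP4, the water channel of astrocyte endfeet, at -0.15 (camera adjusted p = 0.00014, and adjusted p = 0.60 with an estimated correlation). The mean slope of this list was -0.137 ± 0.024 in the dentate gyrus, 0.131 ± 0.034 in the prefrontal cortex and between 0.007 and 0.092 in the other 6 regions. The prefrontal slope was 0.075 ± 0.015 without the 1-year male library, whose list mean of 4.894 lay below the others (5.43 to 5.78). The parietal slope of 0.069 was 0.106 without the 1-year and 0.045 without the 20-year female library, and the cerebellar one 0.017 without the 1-year female and 0.0022 without the 10-year male library. Of 16 oxidative phosphorylation genes 12 and of 18 ribosomal protein genes 14 fell adjusted over the list alone, each with 0 called over all genes (adjusted p = 0.00014 for both, and adjusted p = 0.80 with an estimated correlation for both). Choroid plexus and ependyma genes had a mean slope of -0.237 ± 0.032 there, the steepest of the 31 lists. Of these 6 genes 4 fell adjusted over the list alone, TTR (-0.63), FOLR1 (-0.29), CLIC6 (-0.22) and KL (-0.17), with adjusted p = 0.0017 and adjusted p = 0.60 with an estimated correlation. Of 11 immature neuron genes 3 fell adjusted over the list alone, SOX11 (-0.37) and DPYSL3 (-0.30) among them, and the mean slope was -0.130 ± 0.026 (adjusted p = 0.011, and adjusted p = 0.60 with an estimated correlation). Total RPKM moved with these groups, from a mean of 402926 at 1 and 4 years to 338534 at 10 and 20 years in the dentate gyrus, while it was higher at the later ages in the other 7 regions. The F test of 7 slope differences called 6115 genes in limma, 3065 without the 1-year females, 1842 without the 1-year males, 2684 without the dentate gyrus, 2972 per year of age and 764 within the first set, and 192 of the 6115 were listed at 0 in the second set. The contrast of the dentate gyrus with the other 7 regions, chosen after the data were seen, called 4948 (824 higher, 4124 lower), and 2904 without the 1-year males. The split was 2295 and 1852 with median-ratio scaling and 1944 and 1975 with quantile normalization, so the excess of lower slopes did not hold under either.

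**Figure D4:**
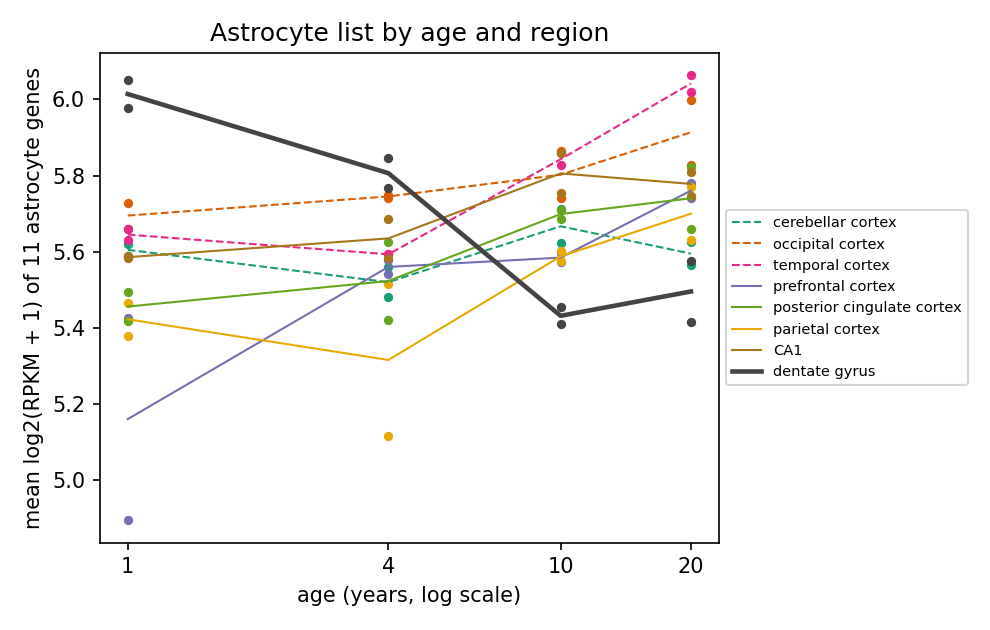
Mean log2(RPKM + 1) of 11 astrocyte genes at 1, 4, 10 and 20 years in 8 regions, each line the mean of the female and male library; dashed lines are the first set and the thick line is the dentate gyrus. The slope was -0.137 ± 0.024 per doubling of age in the dentate gyrus and 0.131 ± 0.034 in the prefrontal cortex, where it was 0.075 ± 0.015 without the library of the 1-year males.

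The age slopes of the cerebellar cortex were compared with the mean of the other 7 regions. PENK, the enkephalin precursor, had a slope 0.61 ± 0.08 higher (limma adjusted p = 4.5e-08), SCG2, a secretory granule protein, 0.47 ± 0.07 higher, and TMEM132B 0.41 ± 0.04 higher (7.0e-12). RPH3A, EGR1, SYN3, B4GALT2 and DOC2A were also higher in slope, of which DOC2A (0.36 ± 0.03) was listed at 0 in the second set. Lower were KCNIP2, a potassium channel partner (-0.38 ± 0.03, 7.0e-12), EPS8 (-0.33 ± 0.03), MAGED4B (-0.32), NAIP (-0.73), KCNH7 (-0.45), RPRML, AK5 (-0.41), and HOXA10, KLHL34, ELMSAN1 and SPNS1. In all, 1460 genes were called, 746 higher and 714 lower, of which 127 were listed at 0 in the second set. The count was 522 without the 1-year females and 920 without the 1-year males, and within the first set alone 931 (520 higher, 411 lower). It was 709 per year of age, 681 among genes with a mean of at least 5 RPKM and 2466 with no filter.

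The sexes differed in 1 gene. ENSMMUG00000029084, which has no symbol in the table, lay between 0 and 0.05 RPKM in 32 female and between 2.68 and 5.8 in 32 male libraries (log2 difference 2.29 ± 0.04, limma adjusted p = 3.0e-09), and so separated all 64 libraries by labelled sex. EIF1AY did not separate the sexes, with 22.9 to 41.7 RPKM in female and 23.1 to 39.3 in male libraries. Not called were CD99, a surface protein of the X and Y chromosomes (40.3 ± 8.83 RPKM in males and 26.7 ± 7.43 in females, SD, n = 4 sets, adjusted p = 0.11), the RNA helicase DDX3X of the X chromosome (34.8 ± 2.39 against 43.7 ± 2.61, adjusted p = 0.61), and RPS4Y2, which had 8.04 ± 0.32 RPKM in males and 11.2 ± 0.46 in females (adjusted p = 0.11). The identifier of the last is named RPS4X in the reference table, so it stood in the lists of both Y genes and X genes. HAUS1, RAB3C and MRPS12 among higher and C1H1ORF51, NR1D1 and EIF2S3 among lower genes in males were among those with the next smallest p.

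Of 8 X genes known to escape inactivation none was called over all genes, and 5 were lower in males adjusted over the list alone. The list median was -0.20, with KDM6A at -0.24, KDM5C and ZFX at -0.20 and SMC1A at 0.03 (camera adjusted p = 1.4e-10, and adjusted p = 0.17 with an estimated correlation). Lists of microglia (adjusted p = 0.0023), glutamate receptors (0.043) and ribosomal proteins (0.045) passed camera with 0 members called by limma and adjusted p = 0.68, 0.68 and 0.81 with an estimated correlation. At an unadjusted p under 0.05, 495 genes differed between the sexes. The count of 1 was 38 with the animal set as a random effect over 64 libraries, 487 with these libraries as independent, 3 with the forebrain or the second set averaged, 4 among genes with a mean of at least 5 RPKM, and 2 without the 1-year or the 20-year males, and with median-ratio scaling 2 genes were higher and 2 lower in males. No sex effect differed between regions in limma (0 calls, 276 at an unadjusted p under 0.05), and EXT1, ELAVL3, TMEM143, CDK10 and CCDC48 had the smallest p. This count was 8 with no filter, 2 with quantile normalization, 2 without the 4-year females and 1 without the 1-year males, the 10-year females or the 20-year females. The age slope differed between the sexes in 1 gene, SNORD113, a small nucleolar RNA named after its values were seen, by -0.61 ± 0.06 in males against females (adjusted p = 0.046, mean level 1.10 RPKM). That count was 0 without the 1-year males, the 4-year females, the 10-year males or either 20-year set, per year of age (240 at an unadjusted p under 0.05), with a pseudocount of 0.1, no filter, a mean of at least 5 RPKM or quantile normalization, and 2 without the 10-year females. FAM162A, SC4MOL, AAAS, IDNK and ZNF222 had the smallest p among genes above 5 RPKM and were not called, and 373 genes had an unadjusted p under 0.05.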

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

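The tests of the dentate gyrus slopes against the other 7 regions, of the scaling behind them and behind their direction, and of single lists as covariates were chosen only after the result was seen.

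The age slope differed between regions for 6115 genes, that of the cerebellar cortex differed from the mean of the other 7 regions for 1460 genes, and the slope in males differed from that in females for 1 gene, SNORD113. The dentate gyrus slope differed from the mean of the other 7 regions for 4948 genes, 4124 of them lower as the values were deposited. A single animal set as the whole cause of the calls is argued against, since leaving out any 1 animal set left at least 2904. With median-ratio scaling 4147 were made (2295 higher, 1852 lower), against 824 higher and 4124 lower as deposited. Slopes that differ were thus found under this scaling too. The test compared totals and not the same genes, and many calls cannot be the same. Scaling therefore stays open as a cause of part of the deposited calls. The excess of lower slopes did not hold, with 44.659% of the calls lower under median-ratio scaling and 50.4% under quantile normalization against 83.3% as deposited, and since both centre the slopes, scaling cannot be told apart from a shift of most genes. Depth stays open, since the U6 step as a covariate was called by limma for 0 of 12039 genes (230 at an unadjusted p under 0.05) and so removed nothing (4908 calls with it and 4965 without in the 5 regions of the second set). With the means of the astrocyte and oligodendrocyte lists as covariates 11 calls were left, below the bound set for this test before its result was seen, with the median effect at 0.19 of its size and the SE 1.48-fold higher. When each list was then run alone, the astrocyte list left the fewest calls (19), and the oligodendrocyte and myelin list left 2985, above that bound. Of the 29 other lists 11 also fell below it, such as interferon response and MHC (139) and oxidative phosphorylation (187). Oligodendrocyte precursors (2053), a glial list, were among these 11. The loss was thus largest with the astrocyte list but not confined to glial lists, and it cannot decide on glia. A changing share of glia in the dissected tissue cannot be told apart from an age effect in its cells, and an age difference of this region stays open and untested.

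Of 96 groups of 8 libraries, 8 held a library far from the others, where chance gives 4.8. The prefrontal library of the 1-year males had a total of 362134 RPKM, with 409169 to 440405 in the other 7. Its astrocyte list had a mean log2 level of 4.894, with 5.43 to 5.78 in the others. The cerebellar library of the 1-year males had a microglia list mean of 2.1883, with 2.44 to 2.55 in the others. The heat shock and protein folding list was high in libraries of the 4-year females: 7.2642 in the cerebellar cortex (others 5.54 to 6.14), 6.7139 in the parietal cortex (5.53 to 6.05), 7.2421 in CA1 (5.67 to 6.35) and 6.7617 in the dentate gyrus (5.59 to 6.03). In the dentate gyrus of the same set the immediate early list had a mean of 2.3731, with 1.29 to 1.58 in the others. The libraries of this set also had the lowest mitochondrial share of their region in 6 of 8 regions.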

How the results depend on the processing

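The tests within sets of regions, those of CA1 and the dentate gyrus each alone, the tests of the dentate slope, of list slopes without single libraries, those without the 1-year or 20-year sets, with age as levels, with constant genes left out, and in other groups of regions (except the 7 forebrain regions) were chosen only after the result was seen. Unless a cause is named, the cause was not tested. Of 3742 values of named genes under other settings 3654 stayed on their side of the threshold, 68 no longer passed and 20 newly passed. Among genes called under either of the settings compared, 0 reversed. Called genes named for region contrasts had been picked for large differences in the same direction in every animal set. For them the choice itself left little room for a reversal when an animal set was left out. Without the 1-year sets 24 of 24 genes named for age no longer passed, in fits with fewer animals. The unknown depth limits what can be said of low genes.

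A pseudocount of 0.1, which weighs low genes more, gave 2537 calls for the hippocampal regions, 599 for dentate gyrus against CA1, 1928 for prefrontal, 2628 for posterior cingulate, 2921 for temporal and 2030 for parietal cortex. It gave 694 for occipital against temporal cortex, 748 for CA1 and dentate gyrus within the second set. It gave 61, 54 and 22 for prefrontal, posterior cingulate and parietal cortex within it. Sex by age was 0 (393 at an unadjusted p under 0.05 in limma). With no filter parietal cortex within the second set had 3, age 1414, age within cerebellar cortex 2, occipital 0 (4204 unadjusted), temporal 15, prefrontal 318, posterior cingulate 111, parietal 6 and CA1 2. The cerebellar slope had 2466, sex by region 8 and sex by age 0 (1052 unadjusted). With a mean of at least 5 RPKM, which tests fewer genes, the counts were 2467 for cerebellar, 1485 occipital, 663 prefrontal, 892 posterior cingulate, 1039 temporal and 732 parietal cortex. They were 1578 for cerebellar cortex and 206 for the hippocampal regions within sets, and 4 for sex. They were 368, 15 and 11 for age in temporal cortex, CA1 and dentate gyrus, 681 for the cerebellar slope and 0 for sex by age (172 unadjusted).

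Median-ratio scaling gave 4 for sex, 690 for age in parietal cortex and 43 in dentate gyrus. Quantile normalization gave 1603 for occipital, 713 prefrontal, 768 posterior cingulate, 1081 temporal and 711 parietal cortex. It gave 760 and 69 for age in parietal cortex and dentate gyrus, 2 for sex by region and 0 for sex by age (426 unadjusted). Robust moderation gave 872, 648, 25 and 10 for age in posterior cingulate, parietal cortex, CA1 and dentate gyrus. Constant genes left out gave 2043, 1039, 896, 225 and 49 for age in prefrontal, posterior cingulate, parietal cortex, CA1 and dentate gyrus. With no block, the pairing by animal set left out, parietal cortex within the second set had 2 calls, and no other count moved by over 1.5 times.

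Per year of age the trend had 15 calls, age by region 2972, the cerebellar slope 709 and sex by age 0 (240 unadjusted). With the animal set as a random effect age had 3823 and sex 38, and with 64 libraries as independent, which counts animals more than once, 6888 and 487. Age as levels gave 16, 0 and 0 for successive steps (1542 and 726 unadjusted for the last ones). Sex had 3 with the 7 forebrain regions and 3 with the second set averaged. Without the 1-year sets age had 1, the cerebellar cortex 1, and occipital 0 (764 unadjusted), temporal 0 (1685), prefrontal 0 (1176), posterior cingulate 0 (1545), parietal 0 (615) and CA1 0 (631). Without the 20-year sets age had 552, cerebellar 25, occipital 221, temporal 13, prefrontal 0 (3551), posterior cingulate 0 (2201), parietal 0 (2410) and CA1 2. Age by region had 2684 without the dentate gyrus and 764 in the first set, and the cerebellar slope 931 there.

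Lists past camera, then with an estimated correlation and by fry, numbered 17, 3 and 26 for cerebellar cortex, 10, 0 and 26 for the hippocampal regions, 7, 0 and 17 for dentate gyrus against CA1. They were 9, 0 and 27 for occipital, 12, 1 and 26 for posterior cingulate, 3, 0 and 25 for temporal and 5, 0 and 25 for parietal cortex, and 0, 0 and 21 for prefrontal cortex. Within sets they were 18, 5 and 26 for cerebellar cortex, 9, 0 and 17 for occipital cortex and 12, 0 and 24 for the hippocampal regions. They were 5, 0 and 17 for prefrontal, 6, 0 and 8 for posterior cingulate and 2, 0 and 0 for parietal cortex. For age they were 7, 0 and 11, and 12 by camera without the 1-year sets, and for sex 4, 0 and 1. For age within regions they were 6, 0 and 0 (cerebellar), 6, 0 and 12 (occipital), 7, 0 and 12 (temporal). They were 9, 0 and 7 (prefrontal), 2, 0 and 3 (posterior cingulate), 12, 0 and 5 (parietal), 4, 0 and 0 (CA1) and 5, 0 and 4 (dentate gyrus). In the planned contrasts lists past both camera and fry in the same direction numbered 14 for cerebellar cortex, 8 for the hippocampal regions and 7 for dentate gyrus against CA1. They numbered 4 for occipital, 1 for posterior cingulate, 0 for temporal and 1 for parietal cortex. Most lists past camera in these 4 contrasts thus did not pass fry in the same direction. An example of camera and the median differing in sign was glutamate receptors in cerebellar cortex (median 0.09, camera lower).

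Leaving out 1 animal set gave 4495 to 4595 for cerebellar cortex, 1308 to 1375 for the hippocampal regions, 206 to 289 for dentate gyrus against CA1. It gave 2735 to 2806 for occipital, 1067 to 1095 prefrontal, 1375 to 1447 posterior cingulate, 1771 to 1882 temporal and 1147 to 1176 parietal cortex. Within sets it gave 2230 to 2284 for cerebellar, 353 to 404 occipital, 338 to 382 hippocampal, 16 to 33 prefrontal, 14 to 23 posterior cingulate and 1 (without 4-year males) to 7 parietal. It gave 539 (without 1-year females) to 2507 for age, 1 to 2 for sex, and 1842 (without 1-year males) to 6564 for age by region. It gave 522 (without 1-year females) to 1576 for the cerebellar slope, 2904 (without 1-year males) to 5025 for the dentate slope, 0 to 2 for sex by region and 0 to 2 for sex by age. Within regions age had 50 to 820 (cerebellar), 23 to 1224 (occipital), 66 to 677 (temporal), 0 to 1054 (prefrontal), 1 to 679 (posterior cingulate), 0 to 573 (parietal), 1 to 10 (CA1) and 0 to 0 (dentate gyrus), the lowest without a 1-year library in each but the last. This lowest count was also reached without the 10-year male or the 20-year female library in the parietal cortex and without the 20-year male library in CA1. In simulated data 46.5% of slopes of 0.2 and 98.5% of slopes of 0.5 were recovered in prefrontal cortex, and 29% of sex by region differences of 0.5.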

Other observations

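The tests of why the cerebellar, occipital and temporal libraries stand apart, those of the genes that move with SPNS1, and that of the region with the most calls, were chosen only after the result was seen.

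Of 64 pairs of a heat shock and protein folding gene and a region, 55 had their highest level in the 4-year females. The exceptions were CRYAB in 6 regions, HSPA8 in the parietal cortex (468 RPKM, highest other 486) and the dentate gyrus (499.97, 572), and BAG3 in the occipital cortex (7.34, 9.13). HSPB1, a small heat shock protein, stood 1.73 to 4.34 times above the median of the other 7 animal sets in all 8 regions. HSPA1B, the inducible HSP70, reached 725 RPKM in the cerebellar cortex, where the highest of the other sets was 124, and 447 RPKM in CA1, where it was 126. HSPH1 reached 128 RPKM in the cerebellar cortex, with 31.1 as the highest of the others. CRYAB, another small heat shock protein, was lower than in the median of the other sets in the temporal cortex (272 against 294 RPKM). The 10 mitochondrially encoded genes took the lowest share of RPKM in this set in 6 of 8 regions, such as 11.6% in the dentate gyrus (others 14.2% to 17.5%) and 10.4% in the prefrontal cortex (12.6% to 15.5%). In the cerebellar cortex (6.996%) and CA1 (12.1%) 1 other library was lower. These libraries were left in all comparisons.

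MBP, the myelin basic protein, stood at 3489 ± 931 RPKM in CA1, 939.9 ± 447 in the occipital, 781 ± 332 in the posterior cingulate, 772 ± 282 in the dentate gyrus, 766 ± 329 in the parietal, 555 ± 103 in the cerebellar, 374 ± 211 in the temporal and 320.4 ± 171 in the prefrontal cortex (SD, n = 8). SST, the interneuron peptide somatostatin, stood at 176 RPKM in the temporal, 117 in the prefrontal and 61.7 in the occipital cortex, and at 89.7 and 76.3 in CA1 and the dentate gyrus.

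The libraries of the cerebellar, occipital and temporal cortex stood apart from the other 40. Regional biology as the whole cause is argued against by the temporal cortex, which correlated better with the cerebellar than with the parietal cortex in 8 of 8 animal sets. Lower depth of the 40 libraries is argued against by 262 genes of at least 10 RPKM in the first set at 0 in all of the second. A different way of assigning reads to genes in the 2 sets may be the source, since the lowest share of U6 values on whole multiples in the second set was 50.562%, above the highest in the first (41.9%). Hits by chance were not taken off these shares. The sources used here do not describe how reads were assigned, and differences between the regions themselves remain within the planned contrasts.

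SPNS1, ELMSAN1, HOXA10, KLHL34 and IRX2 moved together between the 8 libraries of each region, with SPNS1 at 5.79 to 349 RPKM over 64 libraries. For the 10 pairs in 8 regions Pearson's r of log2(RPKM + 1) was 0.921 to 0.99985 and Spearman's rho 0.905 to 1 (r at least 0.835 without the 2 libraries farthest from the median), with no p-value given because the genes were chosen for moving together. Cerebellar RNA in forebrain libraries is argued against by GABRA6, at 0.01 RPKM in the CA1 library with the most SPNS1, where 540.91 would be needed. A source of reads shared in 1 ratio by cerebellar and other libraries is argued against by IRX2, at 0.334 to 0.67206 times KLHL34 in 8 cerebellar and 0.833 to 1.21 times in 16 occipital and temporal libraries. Differences between regions stay open, as genes chosen for moving together cannot test them. Within regions lay 21.97% (first set) and 38.74% (second set) of the variance of log2 SPNS1. A shared source outside the cerebellar cortex stays open too (SD of log2 IRX2 minus log2 KLHL34 0.090266 over 40 libraries, 1.4532 for KLHL34 alone). That pair had the smallest SD of the 10, and HOXA10 with IRX2 the largest (0.297). Age also stays open, since all 5 genes rose in the temporal cortex (slopes 0.263 to 0.288) and 4 had lower slopes in the cerebellar cortex than elsewhere.

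Other splits of the samples were drawn for each count, 100 for each region and age result and all 35 for sex, the real one included. With region labels regrouped within animal sets, 1 of 100 splits, the real one, gave as many calls for the cerebellar cortex (4656, highest other 1796), the hippocampal regions (1334, 775), the dentate gyrus against CA1 (249, 128), and the occipital (2790, 1677), prefrontal (1083, 1008) and posterior cingulate cortex (1412, 1163). For the temporal cortex 2 did (1840, 2092) and for the parietal cortex 3 (1164, 1502). Within the sets it was 1 each for the cerebellar cortex (2375, 997), occipital against temporal cortex (400, 198), CA1 and dentate gyrus (352, 0), and the prefrontal (23, 3), posterior cingulate (19, 4) and parietal cortex (5, 2), and an earlier draw for the last had given 2 of 100. Taken singly, chance is argued against for these, with no adjustment over the results, except for the parietal cortex within its set. Its 5 calls, SPNS1, ELMSAN1, HOXA10, KLHL34 and IRX2, moved together in each region, so their count cannot exclude chance. With ages reassigned within each sex, 1 of 100 gave as many calls for the age trend (2242, 1455), the occipital (1048, 662), temporal (560, 371), posterior cingulate (561, 1) and parietal cortex (323, 8) and the age by region interaction (6115, 5926). It was 2 for the cerebellar cortex (647, 1022), the cerebellar slope (1460, 1517) and the dentate slope (4948, 5138), and 3 for the prefrontal cortex (1242, 1363) and CA1 (9, 99). Taken singly, chance is argued against for these too, again unadjusted. The margin is weak at 2 or 3 of 100, regions included, where other splits gave more calls, and for age by region (6115, 5926). The CA1 count of 9 was also 1 without the 1-year females. The dentate gyrus had been picked from 8 regions, and with the region of most calls taken in each reassignment 2 of 100 gave as many (4948, 5138). With that choice allowed for, chance is argued against at the same weak margin. Chance cannot be excluded for sex by age (8 of 100, real 1, highest other 1037). For the dentate gyrus alone (100 of 100, highest other 817) and sex by region (35 of 35, highest other 4790) the real count was 0, which every split reaches, so the comparison cannot tell. For the sex difference 4 of 35 splits gave 1 call (real 1, highest other 1), so the count does not exclude chance, while the called gene, ENSMMUG00000029084, lay at 0 to 0.05 RPKM in all female and 2.68 to 5.8 in all male libraries. Other splits that called several times the real count, in CA1, the dentate gyrus, sex by age and sex by region, may reflect a structure of the animal sets other than the one tested, which was not looked for.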
